A study of Mus musculus with 16 samples.

How the data were processed

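The material was monoclonal immortalized murine MSC lines with floxed (WT) or deleted (KO) Dicer. Per the labels' protocols, cells were crosslinked with formaldehyde, nuclei were sonicated and histone-bound DNA was pulled down with antibodies before Illumina libraries were made. The series has 16 samples: 12 ChIP libraries, with 3 marks, 2 genotypes and 2 replicates each, and 4 whole-cell extract samples that had no files of their own here. Samples were grouped by mark and genotype and numbered as their titles give it.

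Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to mm9 and peaks were called with MACS, whose version is not given in the sources used here. The authors deposited 24 peak lists, a list against whole-cell extract and a difference list for each ChIP library, called per library and not on pooled replicates. Each peak carries a score deposited by the authors, at least 80 in every list and 3100 for many of the strongest peaks, whose formula is not given in the sources used here. The scores were used to filter peaks and to rank them within a list, never to measure a change between lists. The control of the difference lists is not named in the sources used here. It was taken to be the other genotype of the same mark and number, because 74.6% to 97.7% of the difference peaks had the very coordinates of a peak in the same library's own list, and opposite lists of the same number shared 0 to 10 regions. The direction of every KO-higher or WT-higher call rests on this reading. Shared coordinates name the library of a list and not its control. Opposite lists of different numbers also shared only 0 to 32 regions. A control of the other number, or a pooled one, was therefore not excluded, and comparisons within and between replicates rest on this point. Peaks are called by threshold, so a deeper or better enriched library lists more and wider peaks. No read counts, sequencing depth or extract signal were used here, so this effect could not be removed.

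All overlaps were computed on chromosomes 1 to 19 and X, with an overlap of at least 1 bp. Peaks on unplaced contigs and on chromosome M were left out, and no list held a peak on chromosome Y. For each mark the peaks of the 4 lists against whole-cell extract were merged where they overlapped or touched, which gave the regions. A region was KO-higher or WT-higher in a replicate when it held a peak of that library's difference list. The recurrence of calls between replicates was tested with two-sided Fisher's exact test over the regions, with Wald intervals of the odds ratio. A few of these p-values were below what the software can represent and are given only as odds ratios. The expected counts run over all regions, although most difference peaks were peaks of the library's own list. Regions not listed in a library were thus less open to its calls, though not closed to them. In H3K4me3 KO replicate 1, 18.2% of regions below 1 kb held a difference peak, but only 15.3% were listed. Part of any recurrence follows from listing. Regions with calls in both directions were left out of the comparisons across marks and chromosomes. Peak numbers and covered lengths were compared on the log2 scale with an exact two-sided permutation test. Chromosomes were compared with Fisher's exact test of each against the rest, and p-values were adjusted after Benjamini and Hochberg over 60 tests. Stratified odds ratios are Mantel-Haenszel estimates with a continuity-corrected test. Correlations across chromosomes had 0.5 added to each count and 100000 permutations, and the gap between correlations within and between replicates had 10000 bootstrap draws of chromosomes. Intervals of shares are 95% Wilson intervals.

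The gene annotation at hand was for another mouse build than mm9, and positions are never converted between builds. The planned calls per gene, promoter windows, gene lists and the Dicer1 locus were therefore not analysed here, and regions took the place of promoters and genes. H3K36me3 was taken as neighbouring H3K4me3 within 10 kb. H3K27me3 was required to overlap H3K4me3 where this pair of marks was compared. In counts of loci where every mark differed, H3K27me3 within 10 kb was enough. These distances were set after the data were examined. The rule for named regions was fixed before the data were examined. It takes, per mark and direction, the 5 regions called in both replicates with the highest mean percentile of their strongest difference peak within its list, ties falling to genome order. Many peaks shared the score 3100, so ties were common.

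The recurrence test was tested on simulated lists over the 25204 H3K4me3 regions with 200 seeded regions in 50 runs. Seeded regions were put in both lists, so their 100% recovery was fixed by construction. The mean of 263 regions in both lists against 263 expected checks only the code. Of 50 runs without seeded regions, 3 had a Fisher's exact p under 0.05. Simulated calls were independent, at a share of 0.05 of the regions, against 5206 and 5991 KO-higher regions in the real lists. The error rate in the real lists was therefore not measured. Alternatives were a score of at least 2 times the lowest in the lists (160), merging of peaks within 1 kb, at least 50% of a difference peak inside the region, overlap as a share of peaks, width quartiles as strata, the replicate number as a block, and each replicate left out. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.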

Results

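The data were histone ChIP-seq peak lists from immortalized monoclonal lines of murine mesenchymal stem cells (MSCs), adult stromal cells that grow like fibroblasts. Lines with floxed but intact Dicer (WT) were compared with lines without Dicer (KO), the ribonuclease that cuts microRNA precursors into mature microRNAs. The series title places the work in the study of Let-7, a microRNA family, and its repression of Nr6a1 and of a developmental program of mid-gestation. Antibodies against 3 marks were used: H3K4me3, found at active and poised promoters, H3K36me3, found over the bodies of transcribed genes, and H3K27me3, laid down by Polycomb repressive complex 2. Each mark had 2 libraries per genotype, numbered replicate 1 and 2, which made 12 ChIP libraries. Each library came with a list of peaks against whole-cell extract and with a difference list, taken here as its peaks against the other genotype. Nothing in the labels said that the replicates came from separate cultures or lines, so every value below measures only the spread between these samples. The lists gave no read counts, so the depth of each library was unknown. Positions are mm9 coordinates and no gene was assigned to them.

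The first comparison asked how much of the genome carried each mark in either genotype. H3K4me3 peaks numbered 16737 and 23851 in the KO libraries and 12744 and 18322 in the WT libraries, and they covered 32.3 and 52.7 Mb in KO against 25.1 and 44.1 Mb in WT. H3K36me3 peaks numbered 33417 and 35988 in KO and 38683 and 38104 in WT, over 87.1 and 110.3 Mb against 108.3 and 176.8 Mb. H3K27me3 peaks numbered 706 and 17516 in KO and 2562 and 14955 in WT, over 0.737 and 34.4 Mb against 4.68 and 38.0 Mb. Replicates of H3K27me3 therefore differed far more than the genotypes did. The mean log2 ratio of KO to WT peak number was 0.39 for H3K4me3, -0.15 for H3K36me3 and -0.82 for H3K27me3, with exact two-sided permutation p = 0.667, 0.333 and 1 (n = 2 per genotype). The smallest p this design allows is 0.333, and the H3K27me3 ratio ranged from -3.13 to 1.5 when 1 library was left out.

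**Figure D1:**
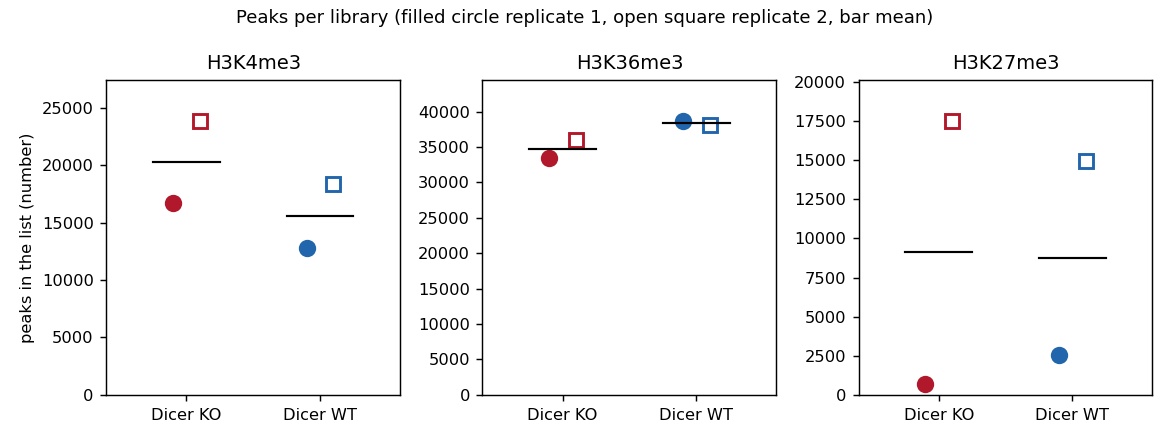
Number of peaks called against whole-cell extract in each of the 12 libraries (vertical axis, peaks), by mark and genotype, with replicate 1 as filled circles, replicate 2 as open squares and the mean of the 2 libraries as a bar. H3K27me3 ranges from 706 to 17516 peaks within the KO genotype, while H3K36me3 stays between 33417 and 38683.

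The libraries were next compared by the base pairs their lists shared, to see whether they grouped by genotype. For H3K4me3 the mean Jaccard index, the shared length over the joint length, was 0.581 within a genotype and 0.618 between genotypes. The highest value of all H3K4me3 pairs, 0.718, joined KO replicate 2 with WT replicate 2. The H3K36me3 means were 0.576 within and 0.546 between genotypes, but the closest pair, at 0.628, was KO replicate 2 with WT replicate 1. The H3K27me3 means were 0.0702 and 0.109, and the closest pair was, as for H3K4me3, replicate 2 of both genotypes, at 0.274. No test was run on these 2 within-genotype and 4 between-genotype pairs. The order turned for H3K4me3 and H3K27me3 when overlap was counted as the share of peaks overlapped, with means 0.0113 and 0.137 higher within than between genotypes. The Jaccard index cannot exceed the ratio of the shorter to the longer list, and H3K4me3 and H3K27me3 replicates differed much in length. It therefore cannot decide whether they grouped by genotype. Of H3K4me3 KO replicate 1 peaks, 98.1% were overlapped by KO replicate 2, 88.5% by WT replicate 2 and 71.9% by WT replicate 1. Of WT replicate 1 peaks, 99.6% were overlapped by WT replicate 2, 99.2% by KO replicate 2 and 94.5% by KO replicate 1.

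H3K4me3 differences that recurred in both replicates lay mostly on the KO side. Of 25204 H3K4me3 regions, made by merging the 4 lists, 2734 held a KO-higher difference peak in replicate 1 and in replicate 2, and 283 held a WT-higher one in both. The KO-higher regions were narrow, with a median width of 1408.5 bp against 1856 bp over all regions, and 3.33% of them were listed in WT replicate 1 and 30.8% in WT replicate 2. The WT-higher regions had a median width of 2289 bp, and 16.6% and 73.9% of them were listed in KO replicates 1 and 2. Among regions listed in all 4 libraries the counts that never went the opposite way were 83 KO-higher and 46 WT-higher.

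The 5 highest-ranked KO-higher H3K4me3 regions were chr2:118998597-119002603, chr2:135566511-135569933, chr5:136145058-136147754, chr6:49159107-49169040 and chr16:22158086-22164816. The first 3 had no H3K4me3 peak in either WT library. The chr6 region was covered over 5354 and 9934 bp in the KO libraries, 0 bp in WT replicate 1 and 1836 bp in WT replicate 2. The 5 highest-ranked WT-higher regions were chr12:105930905-105933171, chr2:54287302-54292528, chr4:63703615-63709399, chr8:123639587-123645100 and chr19:59530611-59536628. The chr12 region was covered over 2136 and 2247 bp in WT and had no peak in either KO library. The other WT-higher regions were listed in KO replicate 2 over 1941 to 3964 bp, against 5227 to 6018 bp in WT replicate 2.

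Replicates picked the same H3K4me3 regions more often than lists independent over all regions would, which in part follows from listing. The 2734 KO-higher regions compared with 1237 expected from 5206 regions in replicate 1 and 5991 in replicate 2 (odds ratio 5.68, 95% CI 5.32 to 6.07). The 283 WT-higher regions compared with 91.8 expected from 1811 and 1278 (odds ratio 4.17, 95% CI 3.62 to 4.80, two-sided Fisher's exact test p = 1.09e-69, and 10.1 with width quartiles as strata). Regions KO-higher in replicate 1 and WT-higher in replicate 2 numbered 18, against 264 expected. Intervals here cover counting error only, and neighbouring regions are not independent: the KO-higher regions fell into 1952 clusters when those less than 100 kb apart were joined. With difference and extract peaks limited to scores of at least 160, the counts were 1295 KO-higher and 179 WT-higher.

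H3K36me3 differences went both ways, with more regions on the WT side. Of 39794 H3K36me3 regions, 266 were KO-higher and 494 WT-higher in both replicates. They were wider than the typical region, with medians of 3929.5 and 4270.5 bp against 2244.5 bp. Adjacent KO-higher regions at chr17:49617452-49628523 and chr17:49628763-49636076 were covered over 11072 and 6433 bp in KO replicate 1 and had no peak in WT. The other leading KO-higher regions were chr6:48781645-48789812, chr6:137424241-137431317 and chr16:22058303-22067728. On the WT side chr4:111098158-111115025 and chr4:111117544-111134361 formed a neighbouring pair with no H3K36me3 peak in KO, and chr3:66024066-66030386 had none either. The remaining leaders, chr3:83570346-83579282 and chr19:28601362-28607871, were covered over 7054 and 935 bp in KO replicate 2 and over 8937 and 6510 bp in WT replicate 2.

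Recurrence between replicates exceeded independence over all regions for H3K36me3 as well. For KO-higher regions 38.8 were expected from 1682 and 918 (odds ratio 10.8, 95% CI 9.27 to 12.6, Fisher's exact p = 2.25e-147), and for WT-higher regions 193 from 2294 and 3349 (odds ratio 3.33, 95% CI 2.99 to 3.71, Fisher's exact p = 6.32e-90). The regions fell into 146 and 258 clusters. With scores of at least 160 the counts were 93 KO-higher and 180 WT-higher. Without the 10 chromosomes that leaned to 1 genotype in this mark (given with the chromosome counts) they were 134 and 183.

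H3K27me3 differences in both replicates were mainly WT-higher. Of 24016 H3K27me3 regions, 904 were WT-higher and 41 KO-higher in both replicates, and none was higher in one genotype in replicate 1 and in the other in replicate 2. The WT-higher regions were broad, with a median of 7116 bp against 1468 bp over all regions. Of these, 9.96% were listed in KO replicate 1, which had 706 peaks in all, but 68.7% were listed in KO replicate 2. The broadest of the leading regions, chr10:50608537-50634701, was covered over 19040 and 26165 bp in WT and had no H3K27me3 peak in KO. The others were chr9:99762884-99781480, chr15:98619126-98628689, chr19:56790557-56807400 and chr19:5554986-5565129, and the chr15 region likewise had no peak in KO. On the KO side the leaders were chr6:52202730-52210525, chr15:102751479-102757571, chr18:89314142-89320545, chr8:81920563-81925398 and chr18:89322282-89326636. The chr15 region on the KO side was covered over 2547 and 6093 bp in KO and had no peak in WT.

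Nearly all regions WT-higher in replicate 1 recurred in replicate 2, with 904 of 967 against 203 expected (odds ratio 65.7, 95% CI 50.8 to 85.0). With width quartiles as strata this odds ratio was 20.2. Neither value takes account of listing. Of the WT replicate 1 peaks 98.7% were overlapped by the WT replicate 2 list, and 9863 regions were listed in KO but not WT in replicate 2. For the KO-higher regions 41 of 97 recurred against 13.2 expected (odds ratio 4.69, 95% CI 3.13 to 7.03, Fisher's exact p = 3.82e-12). Replicate 2 alone gave 3269 KO-higher and 5034 WT-higher regions, so the low KO-higher count rests on the short list of replicate 1. With scores of at least 160 the counts were 9 KO-higher and 514 WT-higher, and without chromosome 18 they were 23 and 887.

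WT-higher calls made up a larger share of the wide H3K27me3 regions than of the narrow ones, a split made after seeing the data. The width of a region comes from all 4 lists, so a broad WT peak itself makes a region wide, and the split is in part fixed by the difference it describes. In replicate 2, regions of 1 to 2 kb were KO-higher in 16.8% and WT-higher in 10.8% of cases. Regions of 5 to 10 kb were KO-higher in 6.14% and WT-higher in 65.4%, and those of 10 to 20 kb in 1.23% and 75.7%. The 85 regions of 20 kb or more were WT-higher in 85.9% of cases in replicate 1 and in 50.6% in replicate 2, and KO-higher in 2.35% and 0%. The length covered in KO replicate 2 relative to WT replicate 2 was 1.49 for regions of 1 to 2 kb and 0.639 for those of 20 kb or more. The widest region of all, chr11:96109987-96219988, was covered over 9.58 and 69.0 kb in KO and 90.6 and 110.0 kb in WT, and like the next 4 in width it was WT-higher in replicate 1 but not in replicate 2.

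**Figure D2:**
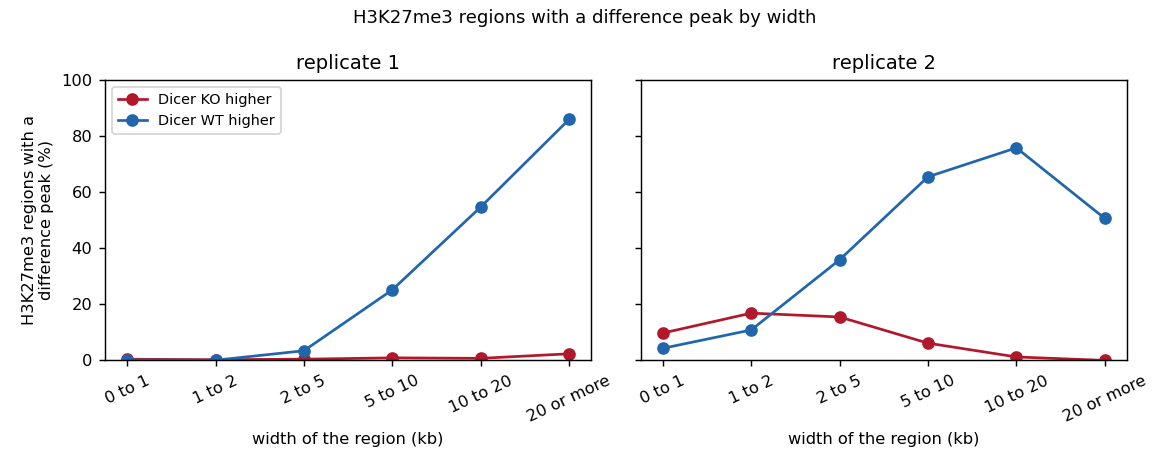
Percentage of H3K27me3 regions (vertical axis) that held a KO-higher (red) or WT-higher (blue) difference peak, by width of the region in kb (horizontal axis), for replicate 1 and replicate 2, each point being 1 width class of the 24016 regions. In replicate 2 the WT-higher share rises from 4.31% below 1 kb to 75.7% at 10 to 20 kb, while the KO-higher share falls from 16.8% at 1 to 2 kb to 0% at 20 kb or more.

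Presence or absence in the lists against whole-cell extract was counted over the same regions, beside the other ways to part the 4 libraries into pairs. H3K4me3 regions listed in both KO libraries and neither WT library numbered 1574, against 71 for the reverse, while 2718 were listed in replicate 2 of both genotypes and in neither replicate 1. H3K36me3 gave 347 KO and 2857 WT regions beside 2587 in replicate 2 of both genotypes. H3K27me3 gave 106 KO and 378 WT regions beside 4507 in replicate 2 of both genotypes. The crossed pairs, KO 1 with WT 2 and KO 2 with WT 1, gave 10 and 10 regions for H3K4me3, 794 and 176 for H3K36me3, and 4 and 2 for H3K27me3. Except for WT in H3K36me3, fewer regions followed a genotype than were listed in replicate 2 of both genotypes. Regions listed in replicate 1 of both genotypes and in neither replicate 2 numbered 0 for H3K4me3, 142 for H3K36me3 and 0 for H3K27me3. The genotype counts of each mark were higher than these. The split by number thus ran only towards replicate 2, whose lists covered more length in every mark and genotype. With scores of at least 160 the KO counts fell to 1022, 194 and 12 for H3K4me3, H3K36me3 and H3K27me3.

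H3K27me3 and H3K36me3 rarely met in the same library, whereas H3K27me3 and H3K4me3 did. Peaks of H3K27me3 overlapped by H3K36me3 made up 0.0457% to 0.156% of each library's list, the highest being 4 of 2558 peaks (95% Wilson interval 0.0608% to 0.401%). Those overlapped by H3K4me3 made up 6.40% and 7.76% in KO and 7.47% and 13.4% in WT. H3K4me3 regions that met a peak of H3K4me3 and a peak of H3K27me3 numbered 66 and 1244 in KO and 227 and 1985 in WT. Both marks together are called bivalent where they oppose each other at a promoter, but here the peaks need not overlap within a merged region. H3K4me3 peaks overlapped by H3K27me3 numbered 41 and 1240 in KO and 185 and 1980 in WT. Of the 1985 regions in WT replicate 2, KO replicate 2 listed both marks at 853 (43.0%) and H3K4me3 alone at 805 (40.6%). It listed H3K27me3 alone at 110 (5.54%) and neither at 217 (10.9%). Of the 1244 in KO replicate 2, WT replicate 2 listed both marks at 853 (68.6%) and H3K4me3 alone at 260 (20.9%). It listed H3K27me3 alone at 104 (8.36%) and neither at 27 (2.17%), so regions dropped out in both directions. Both marks in both WT libraries and not together in either KO library occurred at 60 regions, and the reverse at 9. With scores of at least 160 these counts were 21 and 4.

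Where H3K4me3 was WT-higher, neighbouring H3K36me3 differences were mostly WT-higher, while near KO-higher H3K4me3 they went both ways. Among KO-higher H3K4me3 regions near H3K36me3, 33 (3.83%) lay within 10 kb of a KO-higher H3K36me3 region and 25 (2.90%) near a WT-higher one. Among WT-higher H3K4me3 regions the counts were 3 (3.03%) and 29 (29.3%), and among regions that were neither 107 (0.929%) and 279 (2.42%). The odds ratio was 12.8 (95% CI 3.49 to 46.7, two-sided Fisher's exact test, p = 5.98e-06, Benjamini-Hochberg adjusted p = 7.17e-06 over 6 tests). With chromosomes as strata it was 8.53 (95% CI 1.21 to 60.3), and regions are not independent replicates.

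H3K4me3 differences were also set against those of H3K27me3 at regions where the marks overlapped. Of 2732 KO-higher H3K4me3 regions 115 (4.21%) met H3K27me3, against 133 of 282 WT-higher ones (47.2%) and 2323 of 22190 that were neither (10.5%). Among the 115 KO-higher regions, 44 (38.3%) met a WT-higher H3K27me3 region. Of the 133 WT-higher ones 11 (8.27%) did, and of the 2323 that were neither 583 (25.1%) did. This order holds only among regions that met H3K27me3. Over all regions it was 44 of 2732 KO-higher and 11 of 282 WT-higher ones, the larger share being on the WT-higher side. Among regions that met H3K27me3, the odds ratio between KO-higher and WT-higher ones was 6.87 (95% CI 3.34 to 14.2, Fisher's exact p = 1.30e-08, adjusted p = 2.60e-08). It was 3.82 in replicate 1 alone and ended in replicate 2 alone, where 243 of 342 KO-higher (71.1%) and 369 of 520 WT-higher regions (71.0%) met WT-higher H3K27me3 (odds ratio 1.00, Fisher's exact p = 1). The relation thus rested on replicate 1.

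All 3 marks moved at 5 H3K4me3 regions in 3 loci, where H3K4me3 and a neighbouring H3K36me3 region were KO-higher and an H3K27me3 region within 10 kb WT-higher in both replicates. These regions were picked after their values were seen. At chr6:49159107-49169040, also among the leading H3K4me3 regions, H3K27me3 within 10 kb covered 5780 and 13721 bp in KO and 15558 and 25137 bp in WT, and H3K36me3 covered 2837 and 5385 bp in KO and 0 bp in WT. The second locus held chr11:95841672-95844981 and chr11:95848739-95850827, and no H3K27me3 peak overlapped the former. The third held chr12:58638418-58642696 and chr12:58644215-58648347, with 4145 and 18775 bp of H3K27me3 around the former in WT and 0 bp in either KO library. The reverse in both replicates was found at chr15:102750192-102754530, where H3K27me3 covered 6778 and 20380 bp in KO and 0 and 4574 bp in WT.

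**Figure D3:**
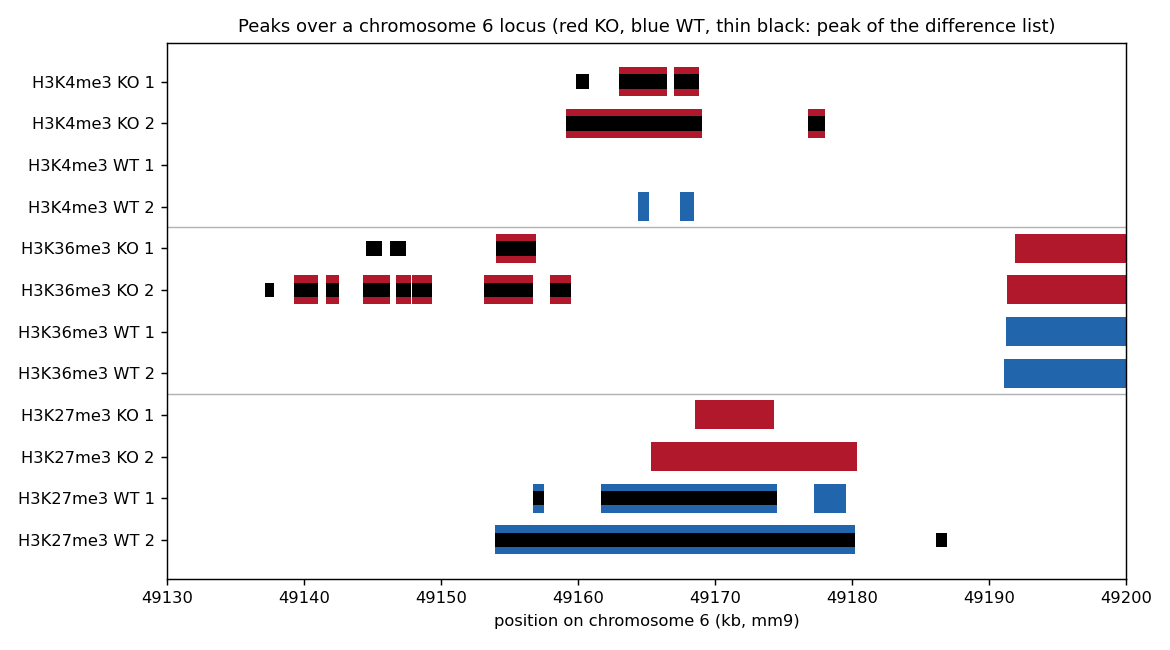
Peaks along a stretch of chromosome 6 (horizontal axis, kb, mm9) in each of the 12 libraries (rows), with peaks against whole-cell extract in red (KO) or blue (WT) and peaks of the difference list as thin black bars. The H3K4me3 peaks cover the region from 49159107 to 49169040 in KO replicate 2 and are missing in WT replicate 1, while H3K27me3 reaches farther to the left in the WT libraries.

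Regions with a recurrent difference were not spread evenly over the chromosomes, which was tested for each mark because clonal lines can differ in copy number. For H3K4me3, KO-higher regions made up 90.6% overall but 63.2% on chromosome 9 (43 against 25), 80% on chromosome 14 and 47.9% on chromosome X (23 against 25), and 96.4% on chromosome 10. For H3K36me3, KO-higher regions made up 35.0% overall but 95.1% on chromosome 12 (39 against 2), 93.9% on chromosome 17 (31 against 2), 3.85% on chromosome 9 (3 against 75) and 0% on chromosome X (0 against 23). Chromosomes 2 and 16 leaned to KO as well, and chromosomes 3, 4, 10 and 19 to WT. For H3K27me3, chromosome 18 held 18 of the 41 KO-higher regions and 17 WT-higher ones. In all, 4, 10 and 1 chromosomes passed Fisher's exact test against the others at an adjusted p under 0.05 over 60 tests, and 10, 18 and 18 did so in replicate 2 alone and 19, 18 and 8 in replicate 1 alone. The test counts neighbouring regions as independent, so these numbers may be too high. The 266 KO-higher and 494 WT-higher H3K36me3 regions formed 146 and 258 clusters, and 6 KO-higher H3K27me3 regions on chromosome 18 lay in 1 cluster.

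**Figure D4:**
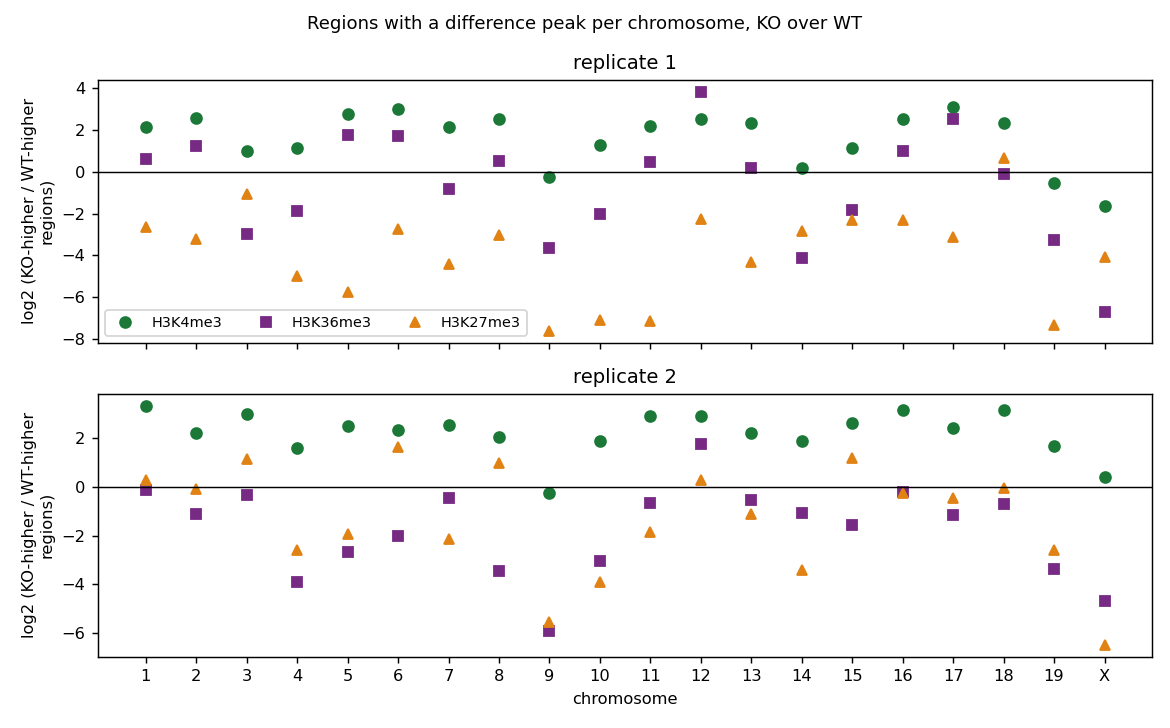
Log2 ratio of the number of KO-higher to WT-higher regions per chromosome (vertical axis, with 0.5 added to each count) for chromosomes 1 to 19 and X, by mark and replicate. H3K4me3 (green) and H3K36me3 (purple) rise and fall together within a replicate, with Spearman's rho 0.925 in replicate 1 and 0.833 in replicate 2.

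The lean of a chromosome was shared by H3K4me3 and H3K36me3 libraries of the same number. Over 20 chromosomes, the log2 ratios of KO-higher to WT-higher regions in these marks correlated with Spearman's rho 0.925 in replicate 1 and 0.833 in replicate 2 (permutation p = 1e-05, the smallest the permutations can give, and 2e-05). Between replicates the rho of these marks was 0.281 to 0.526 and Pearson's r 0.591 to 0.709, against r of 0.936 and 0.864 within replicates 1 and 2. For H3K27me3 against another mark of the same number it was 0.236 to 0.663, and for H3K27me3 of replicate 1 against replicate 2 it was 0.747. These correlations run across chromosomes of single comparisons, and 15 were computed. The H3K27me3 ratios of replicate 1 rest on 97 KO-higher regions, with 0 on chromosomes 9, 10, 11, 19 and X.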

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

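The tests of whole chromosomes, of the number of autosomes, of the KO H3K27me3 peaks found in WT lists and with region width held fixed were chosen after the results were seen. The others were chosen before, but the 10 kb distance and the strata by chromosome that they use were set after the data were examined.

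Peaks of the difference lists outside the assembled chromosomes entered no comparison. On unplaced contigs there were 10 of 5687 and 13 of 6594 H3K4me3 peaks in KO replicates 1 and 2, and 3 of 1867 and 0 of 1334 in WT. For H3K36me3 there were 10 in KO replicate 2 against 1 in KO replicate 1, and 7 and 12 in WT. For H3K27me3 there were 6 in WT replicate 2 and 1 or 0 in each of the others. Counts above 3 were singled out, a limit that takes no account of list length. H3K27me3 WT replicate 1 also held a difference peak on chromosome M from -159 to 6592, with a score of 231, a start that lies before the chromosome's first base.

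The first pattern weighed was the lean of whole chromosomes to one genotype. Noise of single ChIP libraries would leave different marks unrelated, but the lowest rho across chromosomes was 0.833 between H3K4me3 and H3K36me3 of a replicate. It was 0.532 for H3K27me3 with any mark of the other replicate, where no library is shared (5 pairs, permutation test, adjusted p from 0.00115 to 0.0317). Replicate 1 of H3K27me3 had only 97 KO-higher regions, with 0 on chromosomes 9, 10, 11, 19 and X. Its ratios there follow the WT-higher count alone, which limits the pairs that use it. The pair at 0.532 used replicate 2 of H3K27me3. For H3K4me3 and H3K36me3, copy number differences between the KO and WT cells of a replicate may account for the lean (median rho 0.879 within a replicate). Marks of a replicate also share an extract library per genotype, whose noise stays open (lowest rho between replicates 0.281). On the reading of the difference lists taken here, extract enters these counts only through the regions. Base composition of the chromosomes was not tested for these marks. The Dicer genotype alone stays open for them: the median rho was 0.411 between replicates, a gap of 0.468 (95% bootstrap interval over chromosomes 0.176 to 0.879), and the median Pearson's r was 0.621 against 0.900 within them, a gap of 0.280 (0.0972 to 0.609). For H3K27me3 copy number and genotype cannot be told apart. The median rho was 0.377 with the other marks of a replicate and 0.579 between replicates, as genotype alone would give. The gap of -0.202 (-0.490 to -0.0190) runs against a cause shared only within a replicate. The gap in Pearson's r was -0.156 (-0.354 to 0.0373), however, and copy number common to both replicates of a genotype was not tested.

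The second pattern was the low sharing of H3K27me3 regions between KO and WT lists. Background over transcribed chromatin in KO replicate 2 was argued against. Its KO-only regions overlapped H3K36me3 at 0.256 times the share of WT-only regions (4 of 9863 against 13 of 8203, 95% CI of the odds ratio 0.0833 to 0.784). Each share used the H3K36me3 list of its own genotype, 110.3 Mb in KO and 176.8 Mb in WT. The longer WT list can by itself lower that ratio, which was not corrected for. The KO-only share, 0.0406%, does not depend on the WT H3K36me3 list. A weaker KO library that only misses regions was argued against as the whole cause in replicate 2. There 43.6% of 17491 KO peaks overlapped the WT list and KO-only regions outnumbered WT-only ones (9863 against 8203). Spurious peaks of a poorly enriched KO library away from H3K36me3 were not tested. KO-only regions overlapped H3K4me3 at 2.99% against 11.7% for WT-only ones, so a weaker library of that kind stays open. In replicate 1 missed regions stay open as the whole cause (39.3% of 703 KO peaks, 372 KO-only and 1355 WT-only regions). A WT replicate 2 peak also listed in KO replicate 2 outscored one that was not with probability 0.686. That decides nothing, since strong peaks recur in any second list. Exchange of H3K27me3 for H3K4me3 gave an odds ratio of 10.3 for KO-higher H3K4me3 over WT-higher H3K27me3 regions, but these are wide and often carry H3K4me3, and with width held fixed among regions over any H3K4me3 it was 1.81 (95% CI 1.07 to 3.06). In single replicates that ratio was 1.78 (95% CI 1.10 to 2.87) and 1.21 (95% CI 0.896 to 1.62), and WT-higher H3K4me3 gave 0.317 over both replicates, 0.838 in replicate 1 and 1.51 in replicate 2, so exchange stays open.

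The third pattern was the excess of KO-higher over WT-higher H3K4me3 regions. Gains of a few chromosomes were argued against, since KO-higher regions called in both replicates were the more numerous on 19 of 19 autosomes, and those of single replicates on 17 in replicate 1, without chromosomes 9 and 19, and on 18 in replicate 2, without chromosome 9. KO libraries that list more weak peaks cannot be told apart from genotype, because 97.0% of the KO-higher regions were missing from at least 1 of the 4 lists and the ratio was 1.80 (95% CI 1.26 to 2.58) among those listed in all. An effect shared with transcription may hold for part of them, since KO-higher H3K4me3 regions lay near KO-higher H3K36me3 more often than others (odds ratio 3.82, 95% CI 2.56 to 5.72, chromosomes as strata). That involves 33 of 861 regions near H3K36me3, while 25 of the 861 (2.90%) lay near WT-higher H3K36me3, against 2.42% of H3K4me3 regions with no call in both replicates, copy number changes within chromosomes were not tested, and genotype is confounded with clonal line.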

How the results depend on the processing

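The strata by chromosome, the 5 kb distance and the omission of leaning chromosomes were chosen after seeing the data, and the other alternatives before the data were examined. Of 129 alternatives over 34 results, 79 left tests on their side of the threshold, counts within a fixed factor, or ratios and overlaps within their spread. Values within that spread could still change sign, as the H3K27me3 ratio of peak number did. Another 1 ended a call. Among H3K4me3 regions that met H3K27me3, the odds ratio of KO-higher H3K4me3 with WT-higher H3K27me3 was 6.87. It was 1.00 without replicate 1 and 3.82 without replicate 2, and the cause was not tested. The odds ratio of H3K4me3 with H3K36me3 ranged from 8.53 to 47.6 and kept its direction. The other 49 moved a value, mostly counts that fall or rise by construction when fewer peaks or 1 replicate enter. With scores of at least 160, KO-higher and WT-higher regions numbered 1295 and 179 for H3K4me3, 93 and 180 for H3K36me3, and 9 and 514 for H3K27me3. Regions listed in KO libraries only numbered 1022, 194 and 12, regions with both marks in KO or in WT only 4 and 21, and the H3K36me3 log2 ratio of peak number was -0.26. Without leaning chromosomes, H3K36me3 gave 134 KO-higher and 183 WT-higher regions and H3K27me3 23 KO-higher regions. Counted as the share of peaks overlapped, H3K4me3 and H3K27me3 lists overlapped more within than between genotypes, by 0.0113 and 0.137. With width quartiles as strata the recurrence odds ratios of KO-higher and WT-higher regions were 4.19 and 10.1 for H3K4me3, 10.9 and 3.39 for H3K36me3, and 5.38 and 20.2 for H3K27me3.

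With 1 replicate left out, KO-higher regions numbered 5206 to 5991 for H3K4me3, 918 to 1682 for H3K36me3 and 97 to 3269 for H3K27me3. WT-higher regions numbered 1278 to 1811, 2294 to 3349 and 967 to 5034. Regions listed in KO only numbered 4479 to 6784, 2338 to 3452 and 372 to 9863, and in WT only 583 to 1205, 7082 to 17114 and 1355 to 8203. Leaning chromosomes numbered 10 to 19, 18 to 18 and 8 to 18. Regions with both marks in KO only numbered 37 to 391 and in WT only 198 to 1132. The log2 ratio of peak number ranged from 0.12 to 0.65 for H3K4me3, -0.20 to -0.09 for H3K36me3 and -3.13 to 1.5 for H3K27me3, where it changed sign. Covered length of H3K4me3 (-0.10 to 0.72) and H3K27me3 (-4.18 to 1.37) changed sign too. For H3K4me3 this arose where a left-out library broke the balance of numbers, since KO covered more than WT within each number.

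KO and WT samples of the same replicate share only a number, since the labels name no common culture or day. With the replicate number as a replicate block the log2 ratios of peak number stayed at 0.39, -0.15 and -0.82, the SD of the H3K4me3 ratio was 0.0090 against 0.37 without the block, and the smallest sign-flip p is 0.5, so no call could change. Presence of regions deviated together within a number with a correlation of 0.118, 0.00640 and -0.567 for H3K4me3, H3K36me3 and H3K27me3; most H3K27me3 regions are listed in 1 library, which makes that value negative by construction. Not run, for want of an mm9 annotation, were the alternatives on promoter windows, on gene bodies, on calls per gene and on gene lists. The depth of the libraries is unknown, so counts in KO and WT lists cannot be set on 1 depth.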

Other observations

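The X chromosome carried little H3K27me3 and H3K36me3 in the KO lists. Of the H3K27me3 peaks 0.708% and 0.114% lay on X in KO replicates 1 and 2, against 0.976% and 2.73% in WT. For H3K36me3 the shares were 1.08% and 2.06% in KO and 2.78% and 2.83% in WT, and for H3K4me3 2.66% and 2.53% against 3.23% and 2.95%. By share, KO was the lower genotype in each replicate of all 3 marks. By number, H3K4me3 peaks on X were more in KO, with 445 and 603 against 412 and 541 in WT. The H3K27me3 shares of replicate 1 rest on 5 peaks in KO and 25 in WT. The share on chromosome 9 was also lower in KO in each replicate of all 3 marks. For H3K27me3 it was 0.142% and 1.16% in KO (1 and 204 peaks) and 7.22% and 7.22% in WT (185 and 1080 peaks).

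KO-higher H3K27me3 regions were clustered on chromosome 18. The 41 regions formed 29 clusters when those less than 100 kb apart were joined, and the largest held 6 regions at chr18:88829156-88958435. Among H3K36me3 regions, 19 WT-higher ones fell in a single cluster at chr6:83962697-84158952 and 9 KO-higher ones at chr13:118014238-118063741. For H3K4me3 the largest KO-higher cluster held 7 regions at chr7:52660291-52817477.

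When the H3K27me3 call is taken from replicate 2 alone, 7 H3K4me3 regions had both H3K4me3 and H3K36me3 WT-higher within 10 kb of KO-higher H3K27me3, while 1 had all 3 marks WT-higher and 0 had all 3 KO-higher. With H3K27me3 calls in both replicates the 7 became 1, equal to the 1 with all 3 marks WT-higher. One of the 7, chr19:59530611-59536628, was among the leading WT-higher H3K4me3 regions. H3K27me3 around it covered 9346 bp in KO replicate 2 and 0 bp in the other libraries, while H3K36me3 covered 1767 and 5170 bp in WT and 0 bp in KO.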
